A study of Mus musculus with 6 samples.

How the data were processed

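Total RNA from mammary gland was labelled with biotinylated UTP and hybridised to 6 mouse expression arrays, per the labels, with 3 pools at 10 weeks and 3 at 5 weeks. Each pool held RNA of 3 animals, per the series' design text. The deposited values are linear signal intensities, 1 per probe set. On every array the mean without the lowest and highest 2% of probe sets was 500, a property of the deposited intensities tested on the values themselves. The algorithm that made the signals, and any detection call, scan date or batch, is not given in the sources used here. The lowest signal was 0.1 and the highest 15339.6 to 22312.4 on the different arrays. The ratio of 3' to 5' control probe sets was 1.14 to 1.20 for actin and 0.782 to 0.868 for Gapdh. Replicate numbers follow accession order only, so they pair no pools. Because the pools of an age hold different animals, the spread between arrays covers differences between pools and the array step together.

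Of 45101 probe sets, 64 controls were left out. Of the other 45037, 34945 had a single gene symbol, 932 several and 9160 none in the platform annotation used here. Symbols were updated through gene identifiers in a RefSeq table of GRCm38.p6, which matched 34741 of them, and this table was used only for names and for which genes neighbour each other. Probe sets with several symbols or none stayed in the probe set counts (779 of them were called) and out of the gene counts.

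Values under 1 were set to 1, and log2(value + 32) was taken, which understates the differences of dim genes. The array medians lay within 0.118 of each other on the log2 scale, inside the tolerance of 0.2 set in advance, so no further normalization was applied. The 40% of probe sets with the lowest mean were left out, which left 27022. limma 3.58.1 in R 4.3.3 was run with lmFit and eBayes with a variance trend, on age alone, with 4 residual degrees of freedom, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. The brightest probe set stood for each of 13002 genes. Of 5921 genes with several probe sets, 44 had calls in both directions and 1292 had at least 2 calls in 1 direction. The 26 gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg over the lists. Camera with a correlation estimated from the residuals and fry were run beside it. A permutation of pools cannot give a p under 0.1 with 3 against 3.

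The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 largest increases and 12 largest decreases among called genes whose ages do not overlap. From each list it takes the 3 members with the smallest adjusted p in the direction of most calls, and the largest call the other way. In a list without calls it takes the 2 brightest members. Erbb2, Esr1, Pgr, Prlr, Lhcgr, Csn2, Wap and Mki67 are always named. The lists cover milk proteins, fatty acid synthesis, luminal, basal, hormone-sensing and alveolar cells, adipocytes, cell cycle, fibroblasts, ERBB genes, and 16 lists of other cell types and responses.

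The steps were tested on simulated data for the comparison of 10 with 5 weeks, over 27022 probe sets. Of 50 changed probe sets at each size, 0% were recovered at a log2 difference of 0.5, 58% at 1, 90% at 2 and 92% at 3, and 5 of 125 calls were of unchanged probe sets. The data gave 7774 calls, far more than the simulation, so the adjusted threshold was stricter in the simulation. These shares are therefore not the recovery rates in the data. Alternatives changed the offset, the filter, the normalization, the variance model, the array weights, the probe sets of a gene and the list test, and left out each pool in turn. A covariate for skeletal muscle and lists without very bright members were added after the data were seen. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.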

Results

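RNA from mammary glands of female bitransgenic mice was compared between 10 and 5 weeks of age. The mice came from a cross of the LH mouse, as the labels name it, with the MMTV-neu mouse, in which the viral mammary tumour promoter drives the neu (Erbb2) oncogene. Each age had 3 arrays, and each array held pooled RNA from 3 animals, for 9 animals per age. The arrays carried 45101 probe sets, each reported as a linear signal intensity. Median signals lay between 156.4 and 172.5 on the 6 arrays. Correlations of log2 signals were 0.963 to 0.977 between arrays of the same age and 0.874 to 0.926 between ages. The first principal component held 67.3% of the variance and the second 11.1%. No array was a copy of another, and the small number of arrays limits the precision of every value.

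The series was set up to compare the glands at 10 weeks with those at 5 weeks. At 10 weeks, 13 of 17 milk protein genes and 14 of 19 luminal epithelial genes were higher. Lower were 9 of 14 genes of hormone-sensing cells, 21 of 22 of the collagen matrix, 10 of 17 of fat, 8 of 12 of vessels and 4 of 16 of skeletal muscle. The mean shift of the muscle list, -2.03, became -1.02 without 10-week pool 1. These lists were called by camera with a preset correlation, and with an estimated correlation their adjusted p was 0.404 to 0.685. The largest increase was that of Csn1s2b, a casein of milk, whose signal was 7509 ± 4250 (SD, n = 3) at 10 weeks and 164 ± 88.7 (SD, n = 3) at 5 weeks, a log2 difference of 5.16 ± 0.52 (SE). The largest decrease was that of Sned1, an extracellular matrix protein, from 2254 ± 617 (SD, n = 3) at 5 weeks to 36.0 ± 4.44 (SD, n = 3) at 10 weeks, a log2 difference of -5.03 ± 0.21 (SE) that depends on the offset added before the logarithm (-5.89 with an offset of 1 and -4.08 with 100). In all, limma called 1992 of 13002 genes higher and 2436 lower at 10 weeks, and 491 and 866 of these differed by at least 1 on the log2 scale. Among 27022 probe sets tested, 3634 were higher and 4140 lower. The 3 values of 1 age all lay above those of the other for 50.28% of genes, where chance gives 10%.

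After Csn1s2b, the largest increases were those of Sftpd (log2 difference 4.07), a surfactant collectin of innate defence, 1810065E05Rik (3.75) and 1700012B07Rik (3.67). Gldc, a glycine cleavage enzyme, rose by 3.49, and Wfdc3 by 3.45. Olah, the thioesterase that releases medium-chain fatty acids for milk fat, rose by 3.45. Pigr, which carries polymeric antibodies across epithelium, rose from a signal of 1303 ± 803 (SD, n = 3) to 11427 ± 505 (SD, n = 3). The connexin gene Gjb6 rose by 3.27, the sialyltransferase gene St6galnac2 by 3.21, the macrophage elastase gene Mmp12 by 3.20 and Tmem44 by 3.19. After Sned1, Cited1, a transcriptional co-regulator of hormone-responsive ductal cells, fell by 3.70 and the heparin-binding growth factor gene Ptn fell by 3.54. Egr2, an immediate early transcription factor, fell by 3.42, and Rps4l fell by 3.18. Sprr2f fell by 3.04, Thbs4 fell by 2.96, Ido1 fell by 2.93, the calcium channel gene Cacna1g fell by 2.92 and Ptx3 fell by 2.77. Pgam2 (log2 difference -3.27) and Mybpc2 (-2.87) are skeletal muscle genes. For genes near background at 1 age the offset also sets part of the size and the order. These were Cited1, Rps4l, Sprr2f, Thbs4, Ido1 and Cacna1g, with mean signals of 24.0 to 50.7 at 10 weeks, and Mmp12, Tmem44 and 1700012B07Rik, with 45.2 to 66.4 at 5 weeks. The calls of Pgam2 and Mybpc2 were lost when 5-week pool 1 was left out (adjusted p = 0.0937 and 0.0589) or 5-week pool 3 (0.117 and 0.0716).

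**Figure D1:**
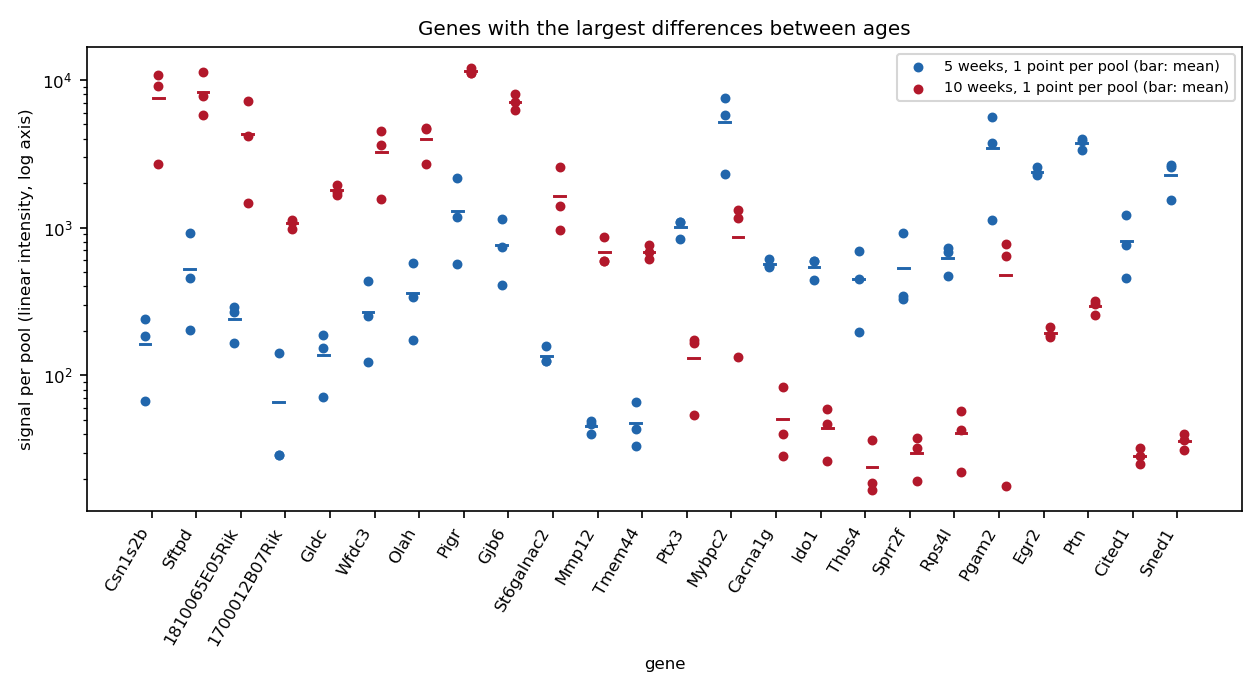
Signal of each pool on a log axis for the genes with the largest increases and decreases, with 3 pools per age as points and their mean as a bar. Sned1 sat at 31.3 to 40.1 in the 10-week pools and at 1542.5 to 2636.2 in the 5-week pools, and Pgam2 and Mybpc2 were spread widely within each age.

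Milk protein genes were higher at 10 weeks. Of 17 measured, 13 rose and none fell (14 rose when adjusted over the list alone), with a median log2 difference of 1.15. Btn1a1, the butyrophilin of the milk fat globule, rose from 4079 ± 767 (SD, n = 3) to 12590 ± 1118 (SD, n = 3), and the mucin gene Muc1 rose by 1.76. Csn2, the beta casein gene, was already among the brightest at 5 weeks, and its signal was 14984 ± 1004 (SD, n = 3) at 10 weeks and 13950 ± 1940 (SD, n = 3) at 5 weeks. Its log2 difference of 0.11 ± 0.11 (SE) did not pass the test (adjusted p = 0.506), and Wap, the whey acidic protein gene, did not either (0.68 ± 0.28, adjusted p = 0.101). The Wap difference was 0.29 without 5-week pool 3 (adjusted p = 0.0806), the pool with the lowest Wap signal (5778.4 against 12492.5 and 13857.1), and passed the test without 5-week pool 1 (0.92, adjusted p = 0.0464). Both genes lay near the top of the signal range. For the milk protein list limma's camera test gave an adjusted p of 2.33e-07, and adjusted p = 0.558 with an estimated correlation.

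Luminal epithelial genes were also higher. Of 19 measured, 14 rose and 1 fell (16 and 2 when adjusted over the list alone), with a median of 0.93. The protease gene St14 rose by 1.73 and its inhibitors Spint1 and Spint2 by 1.70 and 1.26, while the keratin gene Krt7 fell by 0.82. The list had an adjusted p of 5.86e-06 by camera, and adjusted p = 0.558 with an estimated correlation. In the list of alveolar progenitor and prolactin-STAT5 genes, 12 of 17 rose and 3 fell (13 and 3 when adjusted over the list alone), with a median of 0.76. Cd14, a marker of luminal progenitors, rose by 2.01, Sox9 by 1.55 and Tfap2c by 1.30. Socs2, a target and inhibitor of cytokine signalling, fell by 1.02. Camera gave an adjusted p of 0.000199, and adjusted p = 0.404 with an estimated correlation. Genes known from inflamed or involuting glands were higher in 11 of 17 cases and lower in 1 (12 and 1 when adjusted over the list alone), with a median of 0.59. Saa3, an acute phase protein gene, rose by 3.05, Lbp by 1.57 and Clu by 1.30, while Timp1 fell by 0.80. This list had an adjusted p of 0.000376, and adjusted p = 0.558 with an estimated correlation.

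Hormone-sensing luminal genes were lower at 10 weeks. Of 14 measured, 9 fell and 2 rose (10 and 2 when adjusted over the list alone), with a median of -1.02. Pgr, the progesterone receptor gene, fell from a signal of 1268 ± 108.4 (SD, n = 3) to 304.4 ± 39.2 (SD, n = 3), a log2 difference of -1.95 ± 0.14 (SE). Esr1, the oestrogen receptor gene, fell by 0.91, and Foxa1, which encodes a pioneer factor for that receptor, fell by 2.15. Prom1 fell by 2.71, while Cited4 rose by 2.15. Camera gave an adjusted p of 0.00087, and adjusted p = 0.404 with an estimated correlation. The call also ended when the 60% of probe sets with the lowest mean were left out (adjusted p = 0.0552). Prlr and Lhcgr were not analysed here.

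Collagen and fibroblast genes were lower. Of 22 measured, 21 fell (21 when adjusted over the list alone) and none rose, with a median of -0.94. Thbs2, a matricellular thrombospondin, fell from 2685 ± 209 (SD, n = 3) to 568 ± 86.6 (SD, n = 3), Fstl1 fell by 1.53 and the gelatinase gene Mmp2 fell by 1.12. Camera gave an adjusted p of 2.36e-11, and adjusted p = 0.404 with an estimated correlation. Of 17 adipocyte genes, 10 fell and none rose (11 and 1 when adjusted over the list alone), with a median of -0.79. Adipor2, an adiponectin receptor gene, fell by 0.79, Sncg fell by 1.23 and Acvr1c fell by 1.67. Car3, Fabp4, Lpl, Adipoq and Cd36 did not pass the test, with differences of -0.03, -0.04, 0.06, -0.22 and 0.25. Their mean signals were 9666 to 17464, so signal compression could hide larger differences here too. The list had an adjusted p of 0.000938, and adjusted p = 0.576 with an estimated correlation. Of 12 endothelial genes, 8 fell (9 when adjusted over the list alone) and none rose, with a median of -0.65. Vwf fell by 2.03, Flt1 fell by 1.09 and Pecam1 fell by 0.76. The adjusted p was 0.00111, and adjusted p = 0.558 with an estimated correlation.

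Skeletal muscle genes, listed as markers of another tissue that a gland sample could hold, moved in the same direction as the fibroblast, adipocyte and endothelial lists. Of 16 measured, 4 fell and none rose (15 fell when adjusted over the list alone), with a median of -2.06. Casq1 fell by 2.35, Mylpf fell by 2.43 and Myh2 fell by 2.11, and these calls were lost without 5-week pool 1 (adjusted p = 0.0647, 0.0965 and 0.0775) and without 5-week pool 3 (0.0761, 0.112 and 0.11). That of Myh2 was also lost without 10-week pool 1 (0.0705). With a robust variance model these calls, and those of Pgam2 and Mybpc2, were lost as well (adjusted p = 0.111 to 0.157). Their sizes also depended on 10-week pool 1, without which the differences were -1.53 for Casq1, -1.40 for Mylpf, -1.39 for Myh2, -1.97 for Pgam2 and -1.89 for Mybpc2. With no filter the calls of Myh2, Mylpf and Pgam2 were lost (adjusted p = 0.0672, 0.0754 and 0.0729). No variance trend ended them too (0.0519, 0.058 and 0.0555), and an offset of 1 ended that of Pgam2 (0.0557). The mean of the list was 8.89, 11.97 and 11.88 on the log2 scale in the 10-week pools and 13.18, 12.30 and 13.36 in the 5-week pools. Camera gave an adjusted p of 0.00168, and adjusted p = 0.685 with an estimated correlation. The rotation test fry, which tests a list's own direction, gave an adjusted p of 0.176. With the mean of this list as a covariate, an alternative added after the data were seen, 805 genes were higher and 1027 lower. Of the named genes, 20 then lost their calls. The covariate did not overlap between the ages, so it is confounded with age, and a lost call does not tie a gene to muscle. The differences became -0.60 for Casq1, -0.48 for Myh2, -0.32 for Mylpf, -0.78 for Mybpc2, -0.51 for Pgam2, -0.79 for Cox7a1, -0.33 for Cox8b, -0.41 for Ppargc1a and -0.52 for Mcm3. For the others they were -1.10 for Flt1, -0.61 for Pecam1, -0.83 for Mcm5, -0.52 for Top2a, -1.03 for Ighm, -1.07 for Nrg4, -1.35 for S100b, -0.73 for Cyp51, -1.40 for Dbp, 0.46 for Sec61b and 0.42 for Mvd. The differences of Flt1, Dbp and Sec61b were no smaller than without the covariate, while those of the other lost calls were smaller. Of 11 brown fat genes, 5 fell and 1 rose (6 and 1 when adjusted over the list alone). Cox7a1 fell by 1.39, Cox8b fell by 1.26 and Ppargc1a fell by 0.59, while Fabp3, also a gene of milk fat synthesis, rose by 1.93. This list was not called (adjusted p = 0.264) except without 10-week pool 3 (0.0465), and its single calls rested on few pools. That of Cox7a1 was lost without 5-week pool 3 (adjusted p = 0.0529). The difference of Cox8b was -0.70 without 10-week pool 1, and its call was lost without 10-week pool 2 (0.0662) or without any 1 of the 5-week pools (0.0663, 0.116 and 0.106), and that of Ppargc1a without 10-week pool 1 (0.127), 10-week pool 2 (0.0926) or any 1 of the 5-week pools (0.0574, 0.111 and 0.0814). The Cox8b call was also lost with no filter (adjusted p = 0.0901), no variance trend (0.0714) or robust variance (0.146). Array weights (0.0662) and averaged probe sets (0.0529) ended it too. The Ppargc1a call was lost with no filter (0.0746), array weights (0.0514) or averaged probe sets (0.0904).

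**Figure D2:**
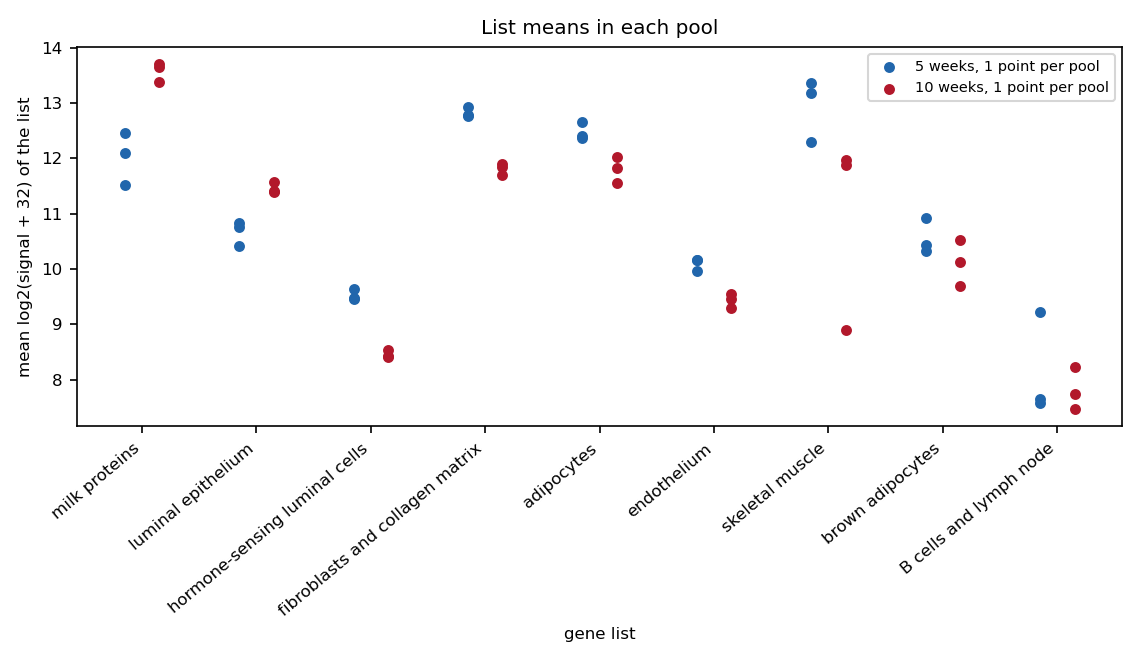
Mean log2(signal + 32) of 9 gene lists in each of the 6 pools, with 1 point per pool. Ages overlapped only for the brown adipocyte list and the B cell and lymph node list, and the skeletal muscle list was lowest in 10-week pool 1, at 8.89.

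Interferon-stimulated genes were lower. Of 15 measured, 8 fell and none rose (9 fell when adjusted over the list alone), with a median of -0.87. Oasl2 fell by 1.36, Irf7 fell by 1.30 and Usp18 fell by 1.16. The adjusted p was 0.00087, and adjusted p = 0.574 with an estimated correlation. In the Wnt and Notch list, 9 of 19 fell and 2 rose (9 and 2 when adjusted over the list alone), with a median of -0.45. Wnt2 fell by 1.96, Hey1 fell by 1.15 and Axin2, a target of Wnt signalling, fell by 0.96, while Wnt5b rose by 1.79. The adjusted p was 0.0225, and adjusted p = 0.404 with an estimated correlation. The Wnt and Notch call ended when the probe sets of a gene were averaged (adjusted p = 0.0531) and with the muscle covariate (adjusted p = 0.068). None of the 26 lists was called with an estimated correlation, where the lowest adjusted p was 0.404 and the lowest unadjusted p 0.0325. In the 11 lists called with the preset 0.01, the estimated correlation ran from -0.005 (Wnt and Notch) to 0.951 (skeletal muscle). It lay well above 0.01 in most of them, so the preset p-values rest on an assumption that the residuals do not bear out. Among the 11 lists called with the preset correlation, 10 were also called by fry, which called 16 in all. The 6 lists that only fry called were plasma cells (0.00996), macrophages (0.0412), skin keratinocytes (0.00144), immediate early and heat shock genes (0.0208), cholesterol synthesis (0.0293) and the unfolded protein response (0.0168). In other splits of the 6 pools into 3 and 3, camera called 5 to 12 lists.

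Camera called none of the other lists. Of 20 genes of fatty acid and triglyceride synthesis, 3 rose and 3 fell (3 and 3 when adjusted over the list alone). Fabp3 rose by 1.93, while Mlxipl, a glucose-responsive transcription factor gene, fell by 1.81, Dgat1 fell by 0.77 and Gpam fell by 0.64 (list adjusted p = 0.495). Of 18 basal and myoepithelial genes, 6 rose and 4 fell (6 and 5 when adjusted over the list alone). Krt14 rose by 1.09, Myh11 by 0.67 and Mylk by 0.60, while Egfr fell by 1.11 (list adjusted p = 0.409). Of 29 cell cycle genes, 2 rose and 4 fell (2 and 4 when adjusted over the list alone). Mcm5 fell by 1.10, Mcm3 fell by 0.90 and Top2a fell by 0.65, while Tpx2 rose by 1.06 (list adjusted p = 0.495). Mki67, a marker of cycling cells, had a log2 difference of 0.18 ± 0.19 (SE) and did not pass the test (adjusted p = 0.514). Of 9 ERBB receptors and ligands, 1 rose and 2 fell (1 and 2 when adjusted over the list alone). Erbb3 rose by 0.83 and Nrg4 fell by 1.34 (list adjusted p = 0.527). Erbb2 had a signal of 588 ± 72.6 (SD, n = 3) at 10 weeks and 565 ± 43.7 (SD, n = 3) at 5 weeks and did not pass the test (adjusted p = 0.81). Whether its probe set also detects the neu transgene is not given in the sources used here.

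Of 8 plasma cell genes, 4 rose and 2 fell (4 and 2 when adjusted over the list alone). Igha, the IgA heavy chain gene, rose from 398 ± 68.1 (SD, n = 3) to 3646 ± 977 (SD, n = 3) and Jchain, which joins antibody polymers, rose by 1.96 (list adjusted p = 0.348). Xbp1 rose by 0.75. Ighm, the IgM heavy chain gene, fell by 1.28 on its brightest probe set, but its probe sets averaged together gave 0.04. Of 16 macrophage genes, 4 rose and 4 fell (4 and 5 when adjusted over the list alone). Cd163, a scavenger receptor gene, fell by 1.70, Folr2 fell by 1.57 and Mrc1 fell by 1.10, while Mpeg1 rose by 0.82 (list adjusted p = 0.495). Of 13 B cell and lymph node genes, none passed the test, nor when adjusted over the list alone (list adjusted p = 0.679). Cd74 had a log2 difference of 0.23 and Cxcl13 of -0.35. The mean of this list was 9.22 in 5-week pool 2 and 7.47 to 8.23 in the other pools. Of 8 T cell genes, 1 fell (1 when adjusted over the list alone), which was Thy1, a gene that fibroblasts also use, by a log2 difference of -1.53 (list adjusted p = 0.982). The median of the T cell list was 0.38 and its mean 0.04, while fry gave it the direction down. This mean became 0.42 without 5-week pool 2, where the list was highest (9.19), and -0.17 without 5-week pool 3.

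Of 7 Schwann cell and nerve genes, 1 rose and 2 fell (1 and 3 when adjusted over the list alone). Mbp fell by 1.78 and S100b fell by 1.57, while Sox10, which epithelium also uses, rose by 1.62 (list adjusted p = 0.439). Of 5 skin keratinocyte genes, 1 fell (1 when adjusted over the list alone), which was Sprr1a, by a log2 difference of -1.63 (list adjusted p = 0.495). Of 18 immediate early and heat shock genes, 4 rose and 5 fell (4 and 6 when adjusted over the list alone). Egr2 fell by 3.42, Egr1 fell by 1.28 and Hspb1 fell by 0.87, while Ier3 rose by 1.25 (list adjusted p = 0.495). Of 13 circadian clock genes, 2 rose and 4 fell (2 and 6 when adjusted over the list alone). Tef fell by 1.09, Dbp fell by 1.12 and Bhlhe40 fell by 0.46, while Hlf rose by 1.32 (list adjusted p = 0.387). The call of Dbp was lost without 10-week pool 2 (adjusted p = 0.052), 5-week pool 1 (0.0677) or 5-week pool 2 (0.0513). That of Bhlhe40 was lost without 10-week pool 2 (0.0961), 10-week pool 3 (0.0944), 5-week pool 1 (0.0503) or 5-week pool 2 (0.0929). The hour of collection is not given by the labels. Of 15 cholesterol synthesis genes, 1 rose and 5 fell (1 and 7 when adjusted over the list alone). Hmgcs1 fell by 0.87, Cyp51 fell by 0.81 and Mvk fell by 0.79, while Mvd rose by 0.55, a call lost without 10-week pool 1 (adjusted p = 0.0597). The list had an adjusted p of 0.104, and was called with no filter (0.0468) and by fry (0.0293). Of 18 genes of the unfolded protein response and secretion, 6 rose and none fell (6 when adjusted over the list alone). Sec61a1, a subunit of the protein channel of the endoplasmic reticulum, rose by 0.77, and Sec61b by 0.44 (list adjusted p = 0.202).

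**Figure D3:**
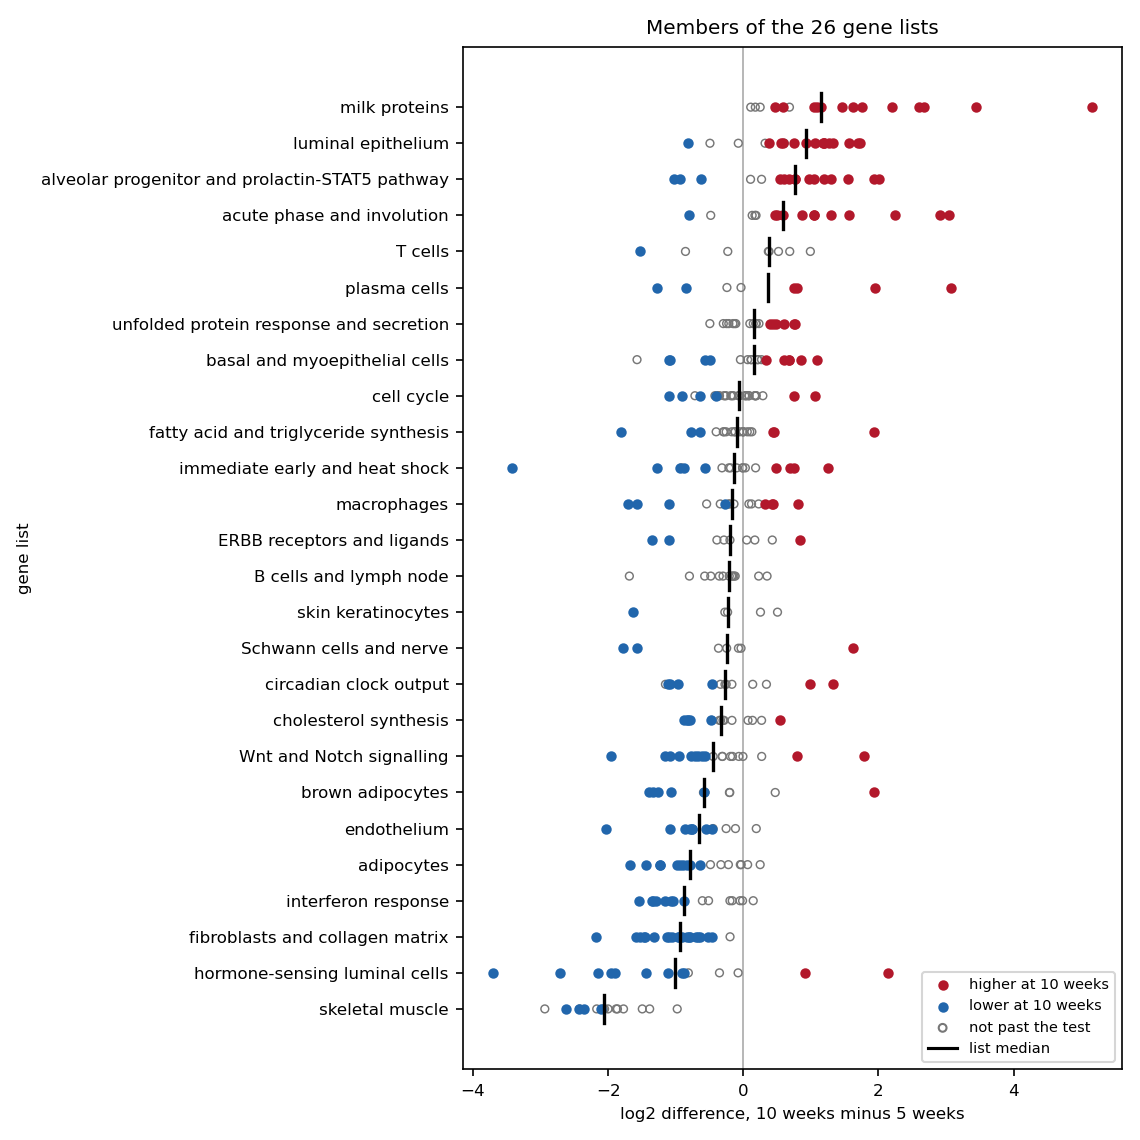
Log2 difference between ages of each member of the 26 gene lists, with filled points for members that passed the test, open points for those that did not and a bar at the median. The fibroblast list had 21 of 22 members lower and the milk protein list 13 of 17 higher.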

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

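The muscle covariate and the lists without bright members were chosen only after the data were seen. The other settings were planned. Leaving out single pools gave 1399 to 1762 genes higher and 1887 to 2033 lower, and shared 71.8% to 78.5% of the genes called with all pools. A fit on fewer arrays has less power, which by itself tends to give fewer calls. An ordinary t statistic per probe set called 2193 higher and 2276 lower. With the muscle covariate 1408 probe sets were higher and 1682 lower, and 805 genes were higher and 1027 lower, at 1 residual degree of freedom less. This covariate did not overlap between the ages. Quantile normalization moved the higher share of called probe sets from 46.7% to 50.3%. Of 1872 values of named genes under the alternatives, 1792 kept direction and side of the threshold, 70 lost the call, 1 gained it and 9 turned. Turned values were 0.20 (Cxcl13) and -0.083 (Erbb2) with the muscle covariate, -0.075 (Csn2) with quantile normalization and 0.039 (Ighm) with averaged probe sets. Without single pools the ranges were -0.77 to 0.33 for Cxcl13, -0.039 to 0.13 for Erbb2, -0.004 to 0.20 for Csn2 and -0.009 to 0.39 for Mki67. The cause was not tested.

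With an estimated correlation the adjusted p was 0.558 for milk proteins and luminal epithelium, 0.404 for hormone-sensing, alveolar progenitor and fibroblast lists and 0.576 for adipocytes. With the 60% filter hormone-sensing cells had 0.0552, while fewer of the dim members were tested. With each array centred on its median signal over the luminal genes, every gene moved down by 1.28 at 10 weeks, more than the luminal genes' own mean difference of 0.79 and median of 0.93. This over-corrects, and a list with a smaller rise turns by construction, so these values bear on no list. Tested with fry, milk proteins had 0.833, fatty acid synthesis 0.00658, cell cycle 0.00126 and ERBB genes 0.00121. The direction turned there for basal cells (0.00098), alveolar progenitors (0.00418), plasma cells (0.0168), T cells (0.0348), acute phase genes (0.0341) and the unfolded protein response (0.00314). The T cell list, not called as first tested, also turned with the offset of 100 (0.96), no filter (0.6), the 60% filter (0.569), quantile normalization (0.981), robust variance (0.967), averaged probe sets (0.95), fry (0.304) and the muscle covariate (0.558). Without single pools the adjusted p was 0.236 to 0.787 for T cells, 0.236 to 0.968 for B cells and 0.175 to 0.877 for fatty acid synthesis, with a turned direction in some. The B cell list also turned with the 60% filter (0.796). With the muscle covariate the cell cycle list (0.735) and the muscle list itself (0.735) turned. The cause was not tested, except for the muscle list, whose own mean was removed. Signals near background limit the dim genes, whose differences the offset understates.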

Other observations

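All gene families below, and the tests of tissue share, scaling, signal compression, single probe sets and splits of probe sets and genes, were chosen only after the result was seen. The neighbour test and the count of lists over splits were set down before, but the signal limits that define the genes of the neighbour test were set later. Of 13 families tested, camera called 6 with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.245. Genes for mucosal antibody transport and antimicrobial proteins were put together with members already seen to rise, such as Sftpd, Pigr, Igha and Jchain, so they were not tested as a group. Of 15 such genes 13 were higher at 10 weeks and 1 lower. Muc4 rose by 2.98, the lactoperoxidase gene Lpo by 2.53, the lactoferrin gene Ltf by 1.46 and Lcn2 by 1.04, while the protease inhibitor gene Slpi fell by 0.66. Of 47 cytosolic ribosomal protein genes 16 rose and 2 fell, with a median of 0.24 as deposited and 0.06 after quantile normalization (adjusted p = 0.000501, and adjusted p = 0.459 with an estimated correlation). Of 37 proteasome subunits 6 rose and none fell, with a median of 0.16 (adjusted p = 0.00554, and adjusted p = 0.459 with an estimated correlation). Among all genes tested, 15.32% were called higher and 18.74% lower, so the share of proteasome genes that rose was near that of all genes. Of 234 solute carriers 67 rose and 43 fell (adjusted p = 0.0432, and adjusted p = 0.245 with an estimated correlation). The zinc transporter genes Slc39a8 and Slc30a2 rose by 2.53 and 1.89, the phosphate transporter gene Slc34a2 by 2.22, and the glutamate transporter gene Slc1a3 fell by 2.07.

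Of 24 ADAM and ADAMTS proteases 11 fell and 1 rose, with a median of -0.51 (camera adjusted p = 0.00554, and adjusted p = 0.245 with an estimated correlation). Adam12 fell by 2.15 and Adamts12 fell by 1.54, while Adam8 rose by 0.75. Of 16 Hox genes 7 fell and none rose (adjusted p = 0.0432, and adjusted p = 0.256 with an estimated correlation). Hoxc4 fell by 2.15, Hoxc5 fell by 1.74 and Hoxc8 fell by 1.70. Of 8 insulin-like growth factors and their binding proteins 5 fell and 1 rose (adjusted p = 0.0432, and adjusted p = 0.256 with an estimated correlation). Igfbp6 fell by 1.59 and Igf1 fell by 1.12, while Igfbp5 rose by 0.55. The directions of these families were the same as deposited, after quantile normalization and after median centring.

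Most of the measured collagen, fat and vessel genes were lower at 10 weeks. A smaller share of stroma and fat with no other change would lower the lists of those cells alike, but the fibroblast list shifted by -0.78 relative to the macrophage list, with a standard error of 0.08 over the pools and 0.20 over the members. Relative to endothelium and adipocytes it shifted by -0.35 and -0.33, with standard errors of 0.12 and 0.15 over the pools and 0.19 and 0.17 over the members, which parts these lists less clearly. A scaling of the arrays that moves all genes alike would lower other genes too. Genes outside every list had a median difference of -0.001, against -0.94 for the fibroblast list. The array medians were already known to lie within 0.118 of each other on the log2 scale. That left little room for another outcome, so this value adds little. The macrophage genes went both ways (4 rose and 4 fell). Cd163, Folr2 and Mrc1 fell by 1.70, 1.57 and 1.10, while Mpeg1 rose by 0.82. The mean of a list so mixed cannot tell whether the share of stroma and fat fell. A change within the cells with age, or a smaller share of stroma and fat beside a change in macrophages, may underlie the pattern, and neither was tested.

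Csn1s1, Csn2 and Csn3, among the brightest transcripts, did not pass the test, while Csn1s2a did. Genes with the highest signals were called about as often as all genes (31.8% against 34.1%). Their median absolute difference was smaller, at 0.225 against 0.306 for genes with a mean of 11 to 12 on the log2 scale. Signal compression could still hide larger differences. Of the 85 genes with the highest signals, 40 had dimmer probe sets to compare with the brightest. The median gain in absolute difference from the brightest to the dimmer probe sets was -0.021 over 1091 genes of middle level. Over the 40 bright genes it was 0.019, with an interval of -0.05 to 0.14. The interval reaches past the bound of 0.1 set for rejecting compression, so the possibility stays open. A smaller change with age in those caseins is open too.

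At 1 age, 46 called genes had signals under 100 and at the other at least 5 times as much, 12 of them higher at 10 weeks and 34 lower. A variant or chromosome segment carried by 1 age group could place such genes side by side, but only Abra and Rspo2 neighboured each other, and a share of 0.3882 of random draws gave as many. That share is above the bound of 0.3 set beforehand for rejecting the explanation, but 8 other signal limits, tried after it was seen, gave 0.082 to 0.8965 in the 5 with any neighbours, so it stays open. A variant under a single probe set might leave the other probe sets level, but the 3 of these genes with others past the filter had a median of 0.521 in the same direction. Over all probe sets, dim ones included, 13 genes had others, of which 7 differed by over 0.5 in the same direction and 2 lay within 0.2 of no difference, and dim probe sets exclude little, so the explanation stays open. A difference with age is open for these genes. So is a difference in the muscle held by the pools, since the skeletal muscle list fell too (median -2.06). Neither was tested apart from these explanations.

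The 6 pools can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The count of probe sets was 7774 in the real split and at most 0 in the others (1 of 10 splits as large), and that of genes 4428 and 0 (1 of 10). The count of lists was 11 in the real split and 12 in the highest of the others, so 2 of 10 splits gave as many. Every other split still holds 2 pools of 1 age against 1 on each side.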
